A study of Mus musculus with 8 samples.

How the data were processed

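Chromatin accessibility was measured by ATAC-seq, with tagmentation by a Nextera kit per the labels' protocols, in 8 libraries of KPshp53 cells. They form 4 groups of 2, control shRNA or p53 shRNA, untreated or treated with 5-aza-2′-deoxycytidine for 48 hours. The shRNA and the replicate number were read from the sample titles, and the treatment from the titles and labels. The replicates are numbered 2 and 3, and nothing in the labels says that a number marks a shared batch.

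The deposited table holds 105458 merged regions of 200 to 2244 bp (median 380) with their genes, CpG islands and distances to gene starts. Per the submitters' processing notes, BWA, MACS2 2.1.0, Subread and DESeq2 were used and the genome build was mm10. The notes do not say which tool made which column. The authors deposited for each region and library a mean coverage and a highest coverage, neither brought to a common library total, and a mark for an interval called in that library. In 98.8% of cases the mean coverage times the number of 32 bp windows in the region, taken as either whole number next to length over 32, was a whole number within 0.0006 per window, so that these values are not read counts. Whether reads had been sampled to one depth beforehand is not stated. The authors also deposited a shrunken log2 fold change for each of 4 comparisons, per the file headers. An adjusted p-value for each comparison was deposited by the authors as well, and none was given for 8198 regions in the comparison of the drug in p53-shRNA cells. All of this was used as deposited, with no step repeated from reads. The build was checked against RefSeq genes on GRCm38.p6. For 85.6% of 91059 region and gene pairs, the deposited distance led to a boundary of the named gene within 1000 bp, and no region lay past a chromosome end.

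The number of sequenced reads is unknown. The sum of mean coverage over regions, by replicate 2 and 3, was 6.27e+06 and 6.57e+06 in shCTR_NT, 6.51e+06 and 6.42e+06 in shCTR_AZA, 5.71e+06 and 5.18e+06 in shp53_NT, and 3.53e+06 and 3.99e+06 in shp53_AZA. The median coverage of a region ran from 19.9 in shp53_AZA replicate 2 to 37.3 in shCTR_AZA replicate 2. Coverage of neighbouring windows shares reads, so counting precision per region cannot be derived from it, and precision was taken from the 2 libraries of each group.

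The tests, gene lists, named-gene rule, alternatives and groups were fixed before the data were examined. A count model had been foreseen, with limma on log2 values as the fallback for a file without counts, and the fallback applied. The minimum of 10 was set once the unit was known. The motifs and the patterns weighed in the closing part were chosen after the first fold changes had been seen. Regions with a deposited mean coverage of at least 10 in at least 2 libraries were kept, which left 104719. Their values were scaled by library total and unweighted trimmed means of log ratios (trim 30% of ratios and 5% of abundances at each end). Log2 of the scaled value plus 1 was fitted in limma 3.58.1 (R 4.3.3) by group in 1 model of all 8 libraries. Moderated tests with a variance trend and robust priors gave 4 pairwise contrasts and the interaction, adjusted by Benjamini-Hochberg over regions with a threshold of 0.05. As 2 libraries per group leave 1 degree of freedom each, the spread was pooled over groups and regions. The code was tested on simulated data made like the comparison of untreated cells. Of 200 changed regions, drawn before a filter that 93655 regions passed, it recovered 27% at a log2 change of 1 and 63% at 2. There were 98 calls, of which 8.16% were false, and 0 calls in an unchanged contrast by limma. Far fewer regions were changed there than were called in the data, so these shares do not give the power of the real comparisons.

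For 18 gene lists of 631 genes in all, of which 557 were named in the file and 359 had a tested region within 1000 bp of their start, the promoter region with the highest mean stood for the gene. Lists were compared with the promoters of the other genes among 12705 by camera in limma with a preset correlation of 0.01, adjusted over 85 tests by Benjamini-Hochberg. The 12705 genes had 11292 promoter regions, and a region shared by several genes entered camera once for each of them (33 genes on 32 regions in the interferon list, 16 on 15 in the imprinted list), whereas counts and medians took each region once. Of 15 calls, 2 were kept and 13 lost when the correlation was estimated. The fibroblast list had 2 promoter regions and was counted but not tested. Region classes (promoters, CpG islands, gene bodies, intergenic regions and the X chromosome) were tested in the same way against all other regions. Agreement between contrasts was given as correlations and overlaps, with 20 simulations of unchanged groups where control libraries were shared. Consensus sites for 16 motifs, of which 8 are reversed consensuses as controls, were searched in the GRCm38 sequence with 2 mismatches allowed in the p53 element. Odds ratios were taken within 10 strata of mean signal (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1, and matplotlib 3.10.9 for the figures).

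Regions were named by rule. From each contrast came the 10 largest rises and 10 largest falls among passing regions with a gene name, a mean at or above the median and no overlap between the libraries of the groups, with no such overlap condition for the interaction and with predicted gene models skipped. From each list came up to 4 passing members with the smallest p, and otherwise up to 2 as values. All regions of Trp53, Cdkn1a and Mdm2 were considered. After the values were seen, naming of list members was further limited to those whose call held without each library in turn, except in the interaction, where 0 of 11 limma calls held.

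The alternatives were median centring, library totals, values as deposited, cyclic loess, no filter, a mean of at least 50, limma without a trend, a log2 change of at least 1, pseudocounts of 0.1 and 5, and a block on replicate number. The others were fits of only the 4 libraries of a contrast, each library left out in turn, promoters within 2500 bp, all regions of a gene, an estimated correlation and limma's fry for the lists. The highest coverage in place of the mean, and list tests with each shared promoter region entered once, were added after the data were seen. Count models were left out because the file holds no counts, and expression was not measured. Tests on other splits of the samples and on single outlying libraries were left out because each group holds 2 libraries. The 22 regions on the Y chromosome were kept.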

Results

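Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in KPshp53 cells, a mouse line derived from pancreatic ductal adenocarcinoma with a mutant Kras. By the sample titles the cells carried a control shRNA or an shRNA against p53, the tumour suppressor encoded by Trp53. All samples, controls included, have the cell line label KPshp53, and the labels do not say whether the shRNA was inducible or its effect was checked, so that knockdown here means the difference between the titles. They were left untreated or given 5-aza-2′-deoxycytidine, an inhibitor of DNA methyltransferases, for 48 hours, which made 4 groups (shCTR_NT, shCTR_AZA, shp53_NT and shp53_AZA). Each group held 2 libraries, which the design text calls biological replicates. The title of the series asks how p53, through metabolism, limits genome instability that comes with R-loops, which are RNA-DNA hybrids. Values are mean coverage over 105458 regions of the mm10 genome, scaled between libraries, and the number of reads behind them is unknown. The sum of mean coverage over the regions ran from 3.53e+06 in shp53_AZA replicate 2 to 6.57e+06 in shCTR_NT replicate 3. After a coverage or a percentage, ± gives the SD over 2 libraries, and after a log2 fold change it gives the SE of the limma fit.

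The authors' peak caller reported an interval in 52295 of the regions in shp53_AZA replicate 2 and in up to 80924 in shCTR_AZA replicate 2. Both replicates of a group shared 66225 regions with an interval in shCTR_NT, 71987 in shCTR_AZA, 51928 in shp53_NT and 47677 in shp53_AZA, and 37109 regions had an interval in all 8 libraries. The regions with an interval in both shCTR_NT libraries and in neither shp53_NT library numbered 15909, against 4356 for the opposite. With the drug, 7681 regions gained an interval in both control-shRNA libraries and 2814 lost it, whereas in p53-shRNA cells 4902 gained and 5690 lost it. These numbers can move with depth, which is unknown, and with signal over background. Coverage summed over regions was lowest in shp53_AZA. Regions without an interval, however, had a median coverage of 9.33 and 9.43 there, against 8.27 and 8.11 in shp53_NT. A lower depth and a weaker signal over background thus cannot be told apart. Replicates correlated across regions at r = 0.957 in shCTR_NT, 0.945 in shCTR_AZA, 0.952 in shp53_NT and 0.924 in shp53_AZA, and libraries of different groups at 0.527 to 0.848, with regions not being independent replicates. The first principal component, with 53.9% of the variance, placed the control-shRNA libraries on one side and the p53-shRNA libraries on the other. The second, with 28.0%, placed untreated and treated libraries apart.

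The first comparison asked what p53 knockdown changed in untreated cells. The regions of Trp53 itself did not pass the test. Within 31 bp of its start, scaled coverage was 135 and 157 in the shCTR_NT libraries and 163 and 155 in the shp53_NT libraries (log2 fold change 0.13 ± 0.13), and the other regions assigned to the gene had log2 fold changes of 0.04 ± 0.10 and -0.09 ± 0.11. An shRNA acts on the messenger RNA, so these values do not measure the knockdown. Regions of Cdkn1a and Mdm2, which are p53 target genes, were among those that changed. The region 42 bp from the start of Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090794 to 29091094, with a p53 response element), fell from 142 ± 34.9 to 8.65 ± 1.44, a log2 fold change of -3.87 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 1.02e-10). Of the 10 regions assigned to Mdm2, the ubiquitin ligase that degrades p53, 8 fell, some of them within the neighbouring gene Cpm. They included the region 601 bp downstream of the Mdm2 start (232 ± 20.9 to 98.6 ± 3.00, log2 fold change -1.22 ± 0.13) and an intronic region at 3754 bp (124 ± 1.46 to 8.32 ± 0.01, log2 fold change -3.75 ± 0.28). The regions at 64 bp (-0.36 ± 0.15) and 7060 bp upstream (0.04 ± 0.11) did not pass the test. Other regions assigned to Cdkn1a moved both ways. The region 10055 bp upstream rose from 3.63 ± 1.74 to 37.9 ± 2.03 (3.12 ± 0.32), the region 10030 bp downstream fell by 2.39 ± 0.28 on the log2 scale, and the regions at 2759 and 4052 bp had log2 fold changes of -0.26 ± 0.10 and 0.46 ± 0.11. The first of these lost its call without each shCTR_NT and each shp53_NT library, the second did not pass after cyclic loess (0.12) or as deposited (0.03), and the region 8778 bp upstream did not pass (0.06 ± 0.40).

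**Figure D1:**
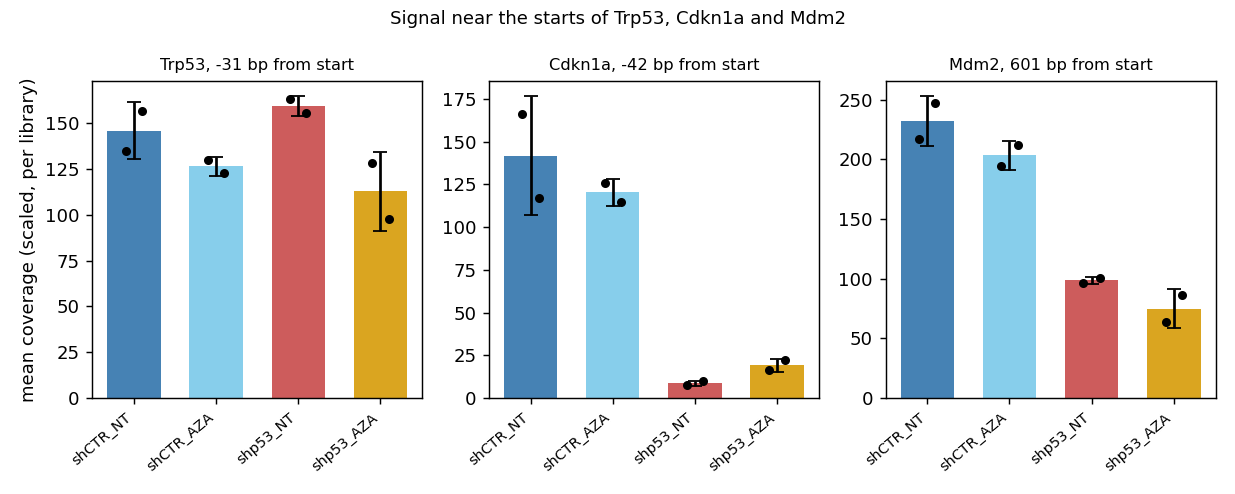
Scaled mean coverage at a region near the start of Trp53, Cdkn1a and Mdm2 in the 4 groups. Bars give the mean of 2 libraries, error bars the SD and points the libraries. The shp53_NT bar lies at 8.65 against 142 in shCTR_NT for Cdkn1a and at 98.6 against 232 for Mdm2.

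Across the genome, 56756 of 104719 tested regions changed in untreated p53-shRNA cells, 30195 of them higher and 26561 lower, and 15875 and 19540 of these by at least 2-fold. The largest rises lay mostly in introns. A region in an intron of Cog3, a Golgi transport gene, rose from 4.07 ± 1.98 to 116 ± 2.01 (log2 fold change 4.59 ± 0.30). A region 18152 bp from the start of Col1a1, the fibrillar collagen chain (chromosome 11, 94953401 to 94955444), rose from 12.3 ± 0.75 to 261 ± 3.98 (log2 fold change 4.30 ± 0.19). The others were near Zfyve26, Shf, Serpinb9, which inhibits granzyme B, Cacna1i, the collagen receptor gene Ddr2, Lpp, Sh3rf1 and Dip2b, with log2 fold changes from 3.84 to 4.33. The largest fall was in an intron of Myo1d, an unconventional myosin (223 ± 1.18 to 5.46 ± 2.67, log2 fold change -5.18 ± 0.27). A region upstream of Igll1 fell from 141 ± 3.09 to 4.68 ± 0.48 (-4.64 ± 0.33). They were followed by regions of Exoc4, Cdkn1a, the mannose receptor gene Mrc1, Mdm2, Prss42, Ubtd1, the acetyltransferase gene Kat2b and Fryl, from -4.16 to -3.53.

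Among promoter regions of fixed gene lists, 49 p53 targets were measured, of which 14 fell and 11 rose, with the same numbers when adjusted over the list alone. Cd80, a T-cell costimulatory ligand, fell by 2.69 ± 0.18 on the log2 scale, whereas Gdf15, a stress-induced cytokine gene, rose (2.00 ± 0.22). The list lay below the promoters of other genes in limma's camera test (Benjamini-Hochberg adjusted p = 6.27e-06, but adjusted p = 0.559 with an estimated correlation). Interferon and viral sensing genes also lay lower (limma camera, Benjamini-Hochberg adjusted p = 8.43e-06, and adjusted p = 0.344 with an estimated correlation), with 9 of 32 lower and 7 higher (9 and 6 adjusted over the list alone). Here Mx2 (-1.32 ± 0.15) and Xaf1 (-1.81 ± 0.29) fell, while the RNA sensor adaptor gene Mavs (0.68 ± 0.08) and the virus tethering gene Bst2 (0.87 ± 0.15) rose. For the AP-1 family of transcription factors, 4 of 12 fell and 2 rose, also adjusted over the list alone, with Jdp2 at 1.06 ± 0.15 and Batf3 at 1.12 ± 0.26 (limma camera, Benjamini-Hochberg adjusted p = 0.0257, and adjusted p = 0.709 with an estimated correlation). Its median was -0.07 and its mean 0.06, and the list did not pass without shCTR_NT replicate 3. Over all regions assigned to the genes instead of their promoter, 14 of the 15 list calls of the 5 comparisons did not pass, with the direction turned for immune markers, and that of epithelial genes under the drug held. Some tests not called over promoters passed there. Housekeeping genes lay above other regions with knockdown (limma camera Benjamini-Hochberg adjusted p = 0.00122 untreated and 0.0244 under the drug). With the drug they lay below (limma camera Benjamini-Hochberg adjusted p = 0.000103 in control-shRNA and 2.45e-06 in p53-shRNA cells), as did AP-1 genes (limma camera Benjamini-Hochberg adjusted p = 7.52e-08 and 0.0359).

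Several lists held many risen promoters, as did all promoters, of which 42.9% rose and 5.41% fell. Of 42 R-loop and replication stress factors, 25 rose. They included Fanca of the Fanconi pathway (0.98 ± 0.11), the checkpoint kinase gene Chek1 (1.15 ± 0.15), the nuclease gene Mus81 (0.69 ± 0.09) and Senp3 (0.60 ± 0.10). Of 33 genes of one-carbon, serine and methionine metabolism, 17 rose. The mitochondrial folate enzyme genes Aldh1l2 (2.06 ± 0.17), Mthfd2 (0.95 ± 0.11) and Mthfd1l (0.89 ± 0.10) and the serine synthesis gene Psat1 (0.90 ± 0.10) were among them. Of 38 genes of the DNA and histone methylation machinery, 16 rose and 1 fell (13 and 1 adjusted over the list alone), with Dnmt3a, a de novo DNA methyltransferase, at 1.02 ± 0.19, and Ezh1, Kdm5b and Setdb2 at 1.04 ± 0.21, 1.00 ± 0.23 and 0.50 ± 0.10. Of 37 cell cycle and replication genes, 18 rose, Ccnb2 by 1.17 ± 0.11, Mcm6 by 0.92 ± 0.14, Ccne2 by 0.95 ± 0.18 and Ccnb1 by 0.80 ± 0.14. Epithelial and classical pancreatic cancer genes rose in 11 of 17 and fell in 1 (12 and 1 adjusted over the list alone), with the keratin genes Krt18 (1.06 ± 0.13) and Krt19 (0.96 ± 0.14), Elf3 (0.82 ± 0.12) and the pancreatic regulator Pdx1 (0.68 ± 0.10). Mesenchymal and basal genes rose in 9 of 18, with Thbs1 (1.00 ± 0.12), Sparc (1.11 ± 0.15), Tgfbi (1.24 ± 0.25) and Itga5 (0.57 ± 0.14). For lists with no second count given, here and in the other comparisons, the numbers were the same when adjusted over the list alone. As deposited, the medians of the R-loop (-0.10), one-carbon (-0.09), methylation machinery (-0.20), cell cycle (-0.07) and mesenchymal (-0.02) lists were below 0, though above that of all regions (-0.38), and after cyclic loess that of the methylation machinery was -0.03.

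None of these 6 lists differed from other promoters in limma's camera test, with Benjamini-Hochberg adjusted p from 0.219 for one-carbon metabolism to 0.953 for the methylation machinery. In the smaller or mixed lists the counts of higher and lower promoters were 3 and 3 of 14 HOX genes, 3 and 1 of 13 germline genes (2 and 1 adjusted over the list alone), 4 and 2 of 18 housekeeping genes, 1 and 1 of 15 imprinted genes (1 higher adjusted over the list alone), 1 and 1 of 6 clustered protocadherins and 1 higher of 4 acinar and endocrine genes. Hoxb9 (1.11 ± 0.20) and Hoxa1 (1.34 ± 0.25) rose and Hoxc5 (-1.24 ± 0.26) and Hoxc4 (-1.34 ± 0.34) fell. The housekeeping genes Ubc (0.81 ± 0.14), Tfrc (0.60 ± 0.11) and Pgk1 (0.52 ± 0.10) rose, although none of them passed as deposited and Pgk1 did not after cyclic loess. Markers of other cell types moved both ways. Of fibroblast markers only Col3a1 (1.08 ± 0.14) and Pdgfrb (1.15 ± 0.28) had a promoter region, too few for a list test, and both rose. Among immune markers Cd68 rose (0.72 ± 0.11) and the lysozyme gene Lyz2 fell (-3.14 ± 0.63), which made 1 higher and 1 lower of 4, and among endothelial markers 1 of 3 rose and 1, the angiopoietin receptor gene Tek, fell (-2.74 ± 0.68). Medians above 0 went with a camera direction below other promoters for germline, imprinted, methylation machinery, endothelial, acinar, HOX and housekeeping genes, of which endothelial markers had a mean of -0.40.

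CpG-island regions rose in 45.9% of cases against 26.6% of other regions, with a median log2 fold change of 0.34, and fell in 3.14% against 28.3%. Limma's camera test placed them above other regions (Benjamini-Hochberg adjusted p = 2.96e-09, but adjusted p = 0.295 with an estimated correlation). Promoters within 1000 bp of a start behaved alike (42.8% higher and 6.09% lower, median 0.31, adjusted p = 3.73e-07 by limma and Benjamini-Hochberg, and adjusted p = 0.295 with an estimated correlation). Intergenic regions fell in 31.3% and rose in 24.2% (median -0.19, limma camera Benjamini-Hochberg adjusted p = 0.0167, and adjusted p = 0.165 with an estimated correlation), while medians were 0.03 in gene bodies and 0.07 on the X chromosome. The CpG-island, promoter and intergenic classes did not pass after cyclic loess. Changes followed the strength of the signal here too. Among 10 equal groups of regions ordered by mean coverage, the weakest had a median of -1.14 with 43.8% of regions lower and the strongest a median of 0.29 with 53.6% higher. The 90th percentile of coverage over the median of regions without an interval in that library served as a rough measure of signal over background. It was 12.6 and 13.7 in the shCTR_NT libraries and 17.5 and 16.2 in the shp53_NT libraries. As those regions are part of the merged set, the number of called intervals and differences between groups can move this ratio too. Scaling set the zero point. The median of all regions was 0.03 as scaled, -0.15 when scaled by library total and -0.38 as deposited, and that of CpG-island regions 0.34, 0.16 and -0.08, with 0.08 after cyclic loess. As deposited, Mavs, Setdb2, Kdm5b, Mus81, Senp3, Pdx1, Itga5, Ccnb1 and Cd68 did not pass, and after cyclic loess Setdb2, Itga5 and Tek did not. In 78.6% of tested regions the libraries of the groups did not overlap, against 33.3% by chance, and the authors' deposited table called 18969 regions higher and 16406 lower.

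The second comparison asked what the drug did in control-shRNA cells. It raised accessibility at single sites by large factors and at promoters of germline genes, and lowered it by smaller amounts at many other promoters. An intronic region of Marf1, a meiosis regulator (chromosome 16, 14131780 to 14132246), rose from 3.34 ± 0.92 to 121 ± 4.89, a log2 fold change of 4.83 ± 0.26 (limma, Benjamini-Hochberg adjusted p = 6.95e-10). An intronic region of the ubiquitin ligase gene Cblb rose from 3.83 ± 0.07 to 105 ± 2.75 (4.46 ± 0.29). The promoter of Stag3, a cohesin subunit of meiosis, rose by 3.45 ± 0.41 and that of Tex19.1, which restrains transposons in germ cells, by 2.69 ± 0.40. Further large rises lay near Kdm1b, a histone demethylase gene, Fnbp1, Vezt, Cox18, Akap9, Iars2, Pik3r1 and Pik3ip1, from 3.44 to 3.82. Falls were smaller, led by introns of Rbpms2 (57.0 ± 2.41 to 16.5 ± 3.41, -1.74 ± 0.25) and Bcl2l13 (-1.65 ± 0.25) and followed by Cubn, Cep110, the cytokine signalling inhibitor gene Socs1, Zc2hc1c, Prkar1b, Htra3, Macrod2 and Tns3, from -1.55 to -1.44. In all, 14397 regions rose and 7942 fell, of which 10200 and 1503 by at least 2-fold. A fit of only the 4 libraries of this contrast gave 17811 higher and 15380 lower regions, so the excess of rises depended on the pooled spread. With each library of these groups left out in turn, the falls lost a larger share of their calls than the rises.

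Of 13 germline genes silenced by promoter DNA methylation, 6 rose, or 8 adjusted over the list alone, with a median log2 fold change of 1.95. This list passed limma's camera test (Benjamini-Hochberg adjusted p = 8.28e-17) and held with an estimated correlation (adjusted p = 0.0318). Of its 55 genes, only these 13 had a tested promoter region, and testing needed a coverage of at least 10 in 2 libraries. At Stag3, with 1.28 and 1.40 in the shCTR_NT libraries, only treated libraries reached it. Such promoters enter through their own rise. Counts and list tests of germline genes with the drug are thus biased towards rises, here and in p53-shRNA cells. Over all 145 regions assigned to these genes the median was -0.01 and the list did not pass. The immune markers passed as well (limma camera, Benjamini-Hochberg adjusted p = 0.0336, but adjusted p = 0.398 with an estimated correlation), with 1 of 4 higher and a median of 0.03 that was below 0 with median centring. Their call was lost without shCTR_AZA replicate 2, without shCTR_NT replicate 3, after cyclic loess and with promoter regions shared by several genes entered once (adjusted p = 0.0513 by limma's camera and Benjamini-Hochberg). Elsewhere falls prevailed, as among all promoters, of which 18.3% fell and 2.27% rose. Lower promoters numbered 11 of 49 p53 targets (3 higher; 12 and 3 adjusted over the list alone), 10 of 37 cell cycle genes, 7 of 38 methylation machinery genes and 6 of 42 R-loop factors. They numbered 6 of 33 one-carbon genes (1 higher; 8 and 1 adjusted over the list alone), 6 of 32 interferon genes (2 higher; 9 and 2 adjusted over the list alone) and 6 of 18 housekeeping genes (10 adjusted over the list alone). They also numbered 5 of 12 AP-1 genes (6 adjusted over the list alone), 4 of 18 mesenchymal genes (6 adjusted over the list alone), 3 of 15 imprinted genes (4 adjusted over the list alone), 2 of 17 epithelial genes and 2 of 4 acinar and endocrine genes. The p53 target Bhlhe40 (-0.59 ± 0.10), the AP-1 genes Junb (-0.53 ± 0.10) and Fos (-0.56 ± 0.10), Tgfb1 (-0.71 ± 0.12), Mus81 (-0.46 ± 0.09) and the glycolytic gene Gapdh (-0.46 ± 0.09) fell, the last not under cyclic loess. There many list medians also came nearer to 0, as from -0.26 to -0.12 for housekeeping, -0.31 to -0.14 for AP-1, -0.24 to -0.12 for cell cycle, -0.27 to -0.17 for R-loop, -0.22 to -0.09 for one-carbon and -0.21 to -0.05 for p53 target genes, but not those of HOX (-0.20 to -0.30), protocadherin, endothelial, epithelial and immune genes. Gdf15 rose (1.19 ± 0.22). Among 14 HOX genes Hoxb9 rose (1.04 ± 0.20) and Hoxd4 fell (-1.22 ± 0.20), and no clustered protocadherin of 6 and no endothelial marker of 3 passed in limma, with 0 also at an unadjusted p under 0.05. Medians below 0 went with a camera direction above other promoters for p53 targets and for interferon, protocadherin, one-carbon, epithelial, mesenchymal, endothelial and HOX genes, of which protocadherins and endothelial markers had means of 0.04 and 0.07. The Cdkn1a region at its start did not pass (-0.21 ± 0.23), while the region 10055 bp upstream rose (1.57 ± 0.32). Of the Mdm2 regions only that 7060 bp upstream passed (-0.66 ± 0.11). Of the Trp53 regions that at 1162 bp fell (-0.43 ± 0.11), and those 31 and 1050 bp upstream had -0.20 ± 0.13 and -0.29 ± 0.10. The call at 1162 bp was lost without shCTR_NT replicate 2, shCTR_AZA replicate 2 or shCTR_AZA replicate 3, after cyclic loess and as deposited.

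CpG-island regions fell in 19.3% of cases against 6.05% of other regions (median -0.26, limma camera Benjamini-Hochberg adjusted p = 2.61e-19, but adjusted p = 0.207 with an estimated correlation), and 1.22% of them rose. Promoter regions had a median of -0.25 (limma camera Benjamini-Hochberg adjusted p = 8.28e-15, but adjusted p = 0.186 with an estimated correlation). Gene bodies rose in 18.0% of cases (median 0.08, limma camera Benjamini-Hochberg adjusted p = 0.00528, but adjusted p = 0.119 with an estimated correlation). Medians were 0.00 for intergenic regions, below 0 with cyclic loess and with median centring, and -0.13 for the X chromosome. After cyclic loess the falls were smaller, with medians of -0.17 for CpG-island and -0.16 for promoter regions, which still passed the camera test, and 6131 regions lower in all. The X chromosome passed there alone (median -0.19). The number of changed regions, 22339, fell to 14147 without shCTR_NT replicate 2, 10460 without shCTR_NT replicate 3, 8334 without shCTR_AZA replicate 2 and 11923 without shCTR_AZA replicate 3. Libraries of the groups did not overlap in 66.3% of regions (33.3% by chance), and of 50 called list members considered for naming only 11 kept their call without each library in turn.

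The third comparison repeated the drug contrast in p53-shRNA cells. Germline promoters opened again, with Stag3 at 4.05 ± 0.41, Tex19.1 at 3.29 ± 0.40 and the meiotic gene Hormad2 at 2.89 ± 0.56. The germ cell RNA-binding gene Dazl had 4.33 ± 0.78, but no coverage in either shp53_NT library, so that the pseudocount of 1 set the size of this value. An intron of Arhgap28 rose from 5.77 ± 1.01 to 95.4 ± 1.44 (3.84 ± 0.26, limma, Benjamini-Hochberg adjusted p = 8.83e-09), and the Marf1 region from 8.69 ± 0.20 to 137 ± 2.59 (3.83 ± 0.26). Regions of Myo10, Dera, Zfhx3, the malic enzyme gene Me1, the phosphate transporter gene Slc20a1, Cblb, Iars2 and Cfdp1 followed, from 3.40 to 3.82. The falls were led by introns of Pter (48.9 ± 3.43 to 5.36 ± 2.20, -3.01 ± 0.27) and Plcl2 (-2.40 ± 0.30), then by Ralgps1, Mnda, Dock4, Samd4, Tktl1, a region of the adipogenic regulator gene Pparg, Cplx3 and Strn, from -2.36 to -2.15. At Cdkn1a the region at the start rose from 8.65 ± 1.44 to 19.2 ± 3.86 (1.06 ± 0.23), and the region 10030 bp downstream rose by 1.68 ± 0.28. The region 10055 bp upstream had 36.5 and 39.4 in the shp53_NT libraries and 103 and 104 in the shp53_AZA libraries. Coverage at 2759 and 4052 bp was lower in both treated libraries than in both untreated ones. At Mdm2 the region 27467 bp downstream, within Cpm, rose from 2.26 ± 0.49 to 31.8 ± 2.20 (3.34 ± 0.40), and the region 64 bp upstream fell (-0.81 ± 0.15). The Trp53 region at 1162 bp fell (-0.47 ± 0.11), and those 31 bp (-0.51 ± 0.13) and 1050 bp upstream (-0.28 ± 0.10) lost their call without shp53_NT replicate 2 or shp53_AZA replicate 3. None of these 3 falls passed after cyclic loess. In all, 19582 regions rose and 19999 fell, of which 15241 and 3558 by at least 2-fold. The authors' deposited table called 8718 regions higher and 6839 lower, with no adjusted p-value for 8198.

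**Figure D2:**
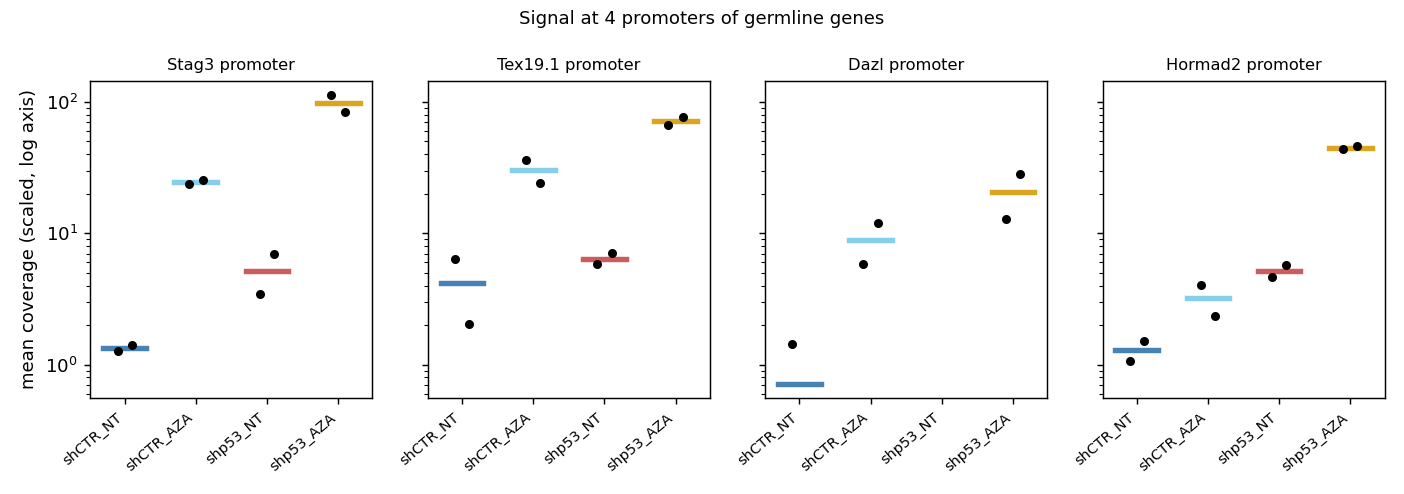
Scaled mean coverage on a log axis at the promoter regions of 4 germline genes in the 4 groups. Lines give the mean of 2 libraries and points the libraries. At Stag3 and Tex19.1 both treated libraries lie above both untreated ones with either shRNA. Libraries with no coverage at Dazl do not appear on the log axis.

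The germline list had 10 of 13 promoters higher, or 10 higher and 1 lower adjusted over the list alone, with a median of 2.89 (limma camera, Benjamini-Hochberg adjusted p = 2.07e-18, which held with an adjusted p = 0.0318 with an estimated correlation). Coverage was below 10 in all untreated libraries at Stag3, Tex19.1, Hormad2 and Dazl, so these were tested only through their rise. Interferon and viral sensing genes rose in 7 and fell in 6 of 32, also adjusted over the list alone (median 0.03, -0.01 with median centring and -0.38 as deposited, limma camera Benjamini-Hochberg adjusted p = 3.64e-08, but adjusted p = 0.214 with an estimated correlation). The antigen presentation genes H2-K1 (0.92 ± 0.12) and Psmb8 (1.60 ± 0.25) rose, and Mavs (-0.55 ± 0.08) and Irf1 (-0.56 ± 0.12) fell, though neither fall passed with cyclic loess. Clustered protocadherins had 1 higher and 2 lower of 6, Pcdhga12 at 2.21 ± 0.43 (median 0.33, -0.06 as deposited; limma camera Benjamini-Hochberg adjusted p = 0.009, but adjusted p = 0.389 with an estimated correlation). For epithelial genes, with 3 higher and 2 lower of 17, and HOX genes, with 1 and 1 of 14, medians of -0.28 and -0.10 went with a camera test above other promoters (limma, Benjamini-Hochberg adjusted p = 0.0293 and 0.00952, but adjusted p = 0.389 and 0.44 with an estimated correlation). After cyclic loess the protocadherin, epithelial and HOX lists did not pass, nor did the epithelial list without shp53_NT replicate 3 or with shared promoter regions entered once (adjusted p = 0.0513 by limma's camera and Benjamini-Hochberg). The HOX median was 0.01 when scaled by library total. Pdx1 (-0.85 ± 0.10), Foxa3 (-0.71 ± 0.14) and Hoxd4 (-1.03 ± 0.20) fell.

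Most other promoters fell, 63.3% of all, with 4.45% higher. Lower promoters numbered 33 of 42 R-loop and replication stress factors (35 adjusted over the list alone), with Fanca at -0.77 ± 0.11, the replication protein gene Rpa1 at -0.68 ± 0.10, the RNA-DNA helicase gene Setx at -0.75 ± 0.11 and Mus81 at -0.61 ± 0.09. They numbered 31 of 49 p53 targets (4 higher; 32 and 4 adjusted over the list alone), among them Foxo3 (-0.73 ± 0.10), the thiamine transporter gene Slc19a2 (-0.88 ± 0.12) and Ptpn14 (-0.79 ± 0.12), while Cd80 rose (1.16 ± 0.18). They numbered 31 of 37 cell cycle genes (32 adjusted over the list alone), with Ccnb1 at -0.90 ± 0.14, E2f7 at -0.71 ± 0.12, Mcm10 at -0.67 ± 0.12 and Mybl2 at -0.53 ± 0.09. They numbered 28 of 38 methylation machinery genes (30 adjusted over the list alone), with the dioxygenase gene Tet3 at -1.22 ± 0.19, the histone methyltransferase gene Dot1l at -0.67 ± 0.10, Setdb2 at -0.58 ± 0.10 and Kdm4b at -0.50 ± 0.07. Of one-carbon genes 24 of 33 fell and 3 rose, with Mthfd1l at -0.64 ± 0.10, the spermidine synthase gene Srm at -0.74 ± 0.12, Mthfr at -0.59 ± 0.10 and Mthfd1 at -0.50 ± 0.09. Mesenchymal genes fell in 8 of 18 (9 adjusted over the list alone), with Snai1 (-0.78 ± 0.11), Axl (-0.66 ± 0.11), Itga5 (-0.78 ± 0.14) and Tgfb1 (-0.62 ± 0.12). Housekeeping genes fell in 12 of 18 (13 adjusted over the list alone), with Hmbs (-0.86 ± 0.14), Ubc (-0.85 ± 0.14), Gusb (-0.72 ± 0.13) and Gapdh (-0.48 ± 0.09). AP-1 genes fell in 7 of 12, with Fosl2 (-0.49 ± 0.09) and Junb (-0.45 ± 0.10). Imprinted genes fell in 6 of 15, with Zfp64 (-0.68 ± 0.12), Inpp5f (-0.62 ± 0.12) and Ube3a (-0.61 ± 0.12). The fall of these lists was smaller after cyclic loess. Their medians went from -0.51 to -0.20 for R-loop factors, -0.42 to -0.13 for p53 targets, -0.47 to -0.14 for cell cycle genes, -0.56 to -0.24 for the methylation machinery, -0.48 to -0.17 for one-carbon genes, -0.41 to -0.24 for mesenchymal genes, -0.35 to -0.01 for housekeeping genes, -0.31 to 0.02 for AP-1 genes and -0.32 to -0.06 for imprinted genes. Both the acinar and endocrine genes called of 4, Mafa (-0.71 ± 0.10) and Isl1 (-0.56 ± 0.12), fell, immune markers had 2 higher and 1 lower of 4, the latter Cd68 (-0.51 ± 0.11), and no endothelial marker of 3 passed in limma, with 0 also at an unadjusted p under 0.05. Medians below 0 went with a camera direction above other promoters also for p53 targets and for imprinted, mesenchymal and acinar genes.

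CpG-island regions fell in 65.5% of cases against 13.04% of other regions (median -0.50, limma camera Benjamini-Hochberg adjusted p = 3.54e-34, but adjusted p = 0.143 with an estimated correlation). Promoter regions had a median of -0.46 (limma camera Benjamini-Hochberg adjusted p = 3.83e-25, but adjusted p = 0.139 with an estimated correlation) and gene bodies one of 0.10 (limma camera Benjamini-Hochberg adjusted p = 0.00613, but adjusted p = 0.119 with an estimated correlation). Gene bodies did not pass after cyclic loess. CpG-island and promoter regions did, with medians nearer to 0 (-0.25 and -0.22), and the number of lower regions went from 19999 to 12556. X-chromosomal regions lay lower (median -0.28, limma camera Benjamini-Hochberg adjusted p = 0.00427), which held with an estimated correlation (adjusted p = 0.0418). Responses followed the strength of the signal. Among 10 equal groups of regions ordered by mean coverage, the weakest had a median of 0.84 with 34.2% of regions higher and the strongest a median of -0.38 with 64.9% lower, against medians of 0.34 and -0.21 in control-shRNA cells. After cyclic loess the falls named for Mthfr, Mthfd1, Kdm4b, Setdb2, Mus81, Foxa3, Tgfb1, Inpp5f, Ube3a, Cd68, Isl1, Fosl2, Junb, Mybl2 and Gapdh did not pass. Of 59 called list members considered for naming, 49 kept their call without each library in turn and 31 under each other scaling, and the median of all regions was -0.41 as deposited against -0.02 as scaled. Libraries did not overlap in 65.7% of regions (33.3% by chance).

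**Figure D3:**
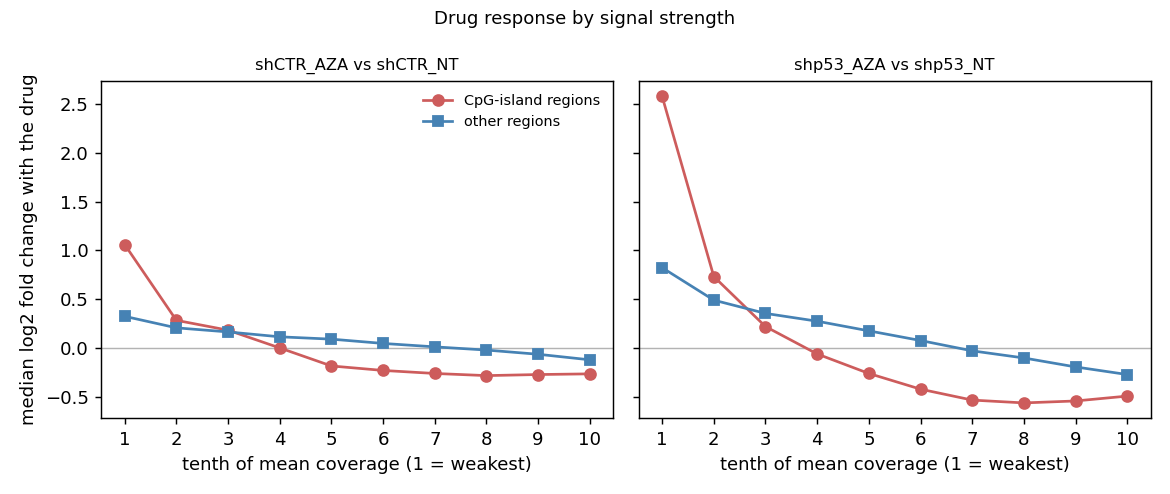
Median log2 fold change with the drug over 10 equal groups of regions ordered by mean coverage, for CpG-island regions and other regions, in control-shRNA cells and p53-shRNA cells. In the weakest group, which holds 147 CpG-island regions, their median was 1.06 and 2.58, and in the strongest it was -0.27 and -0.50. Mean coverage was taken over all 8 libraries, treated ones included.

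The fourth comparison asked what p53 knockdown changed under the drug. The Cdkn1a region at its start stayed lower, at 19.2 ± 3.86 against 120 ± 7.71 (-2.60 ± 0.23, limma, Benjamini-Hochberg adjusted p = 5.15e-08), as did the Mdm2 regions at 601 bp (-1.44 ± 0.13) and 3754 bp (-2.81 ± 0.28) and the promoter of the apoptosis gene Bax (-1.26 ± 0.13). In all, 7 of the 10 Mdm2 regions were lower, and that 7060 bp upstream was higher (0.30 ± 0.11), but not without either shCTR_AZA library, after cyclic loess or as deposited (-0.62). The region near Col1a1 was again higher, at 322 ± 78.4 against 10.2 ± 1.13 (4.83 ± 0.19), followed by regions of Shf, Celf5, the ectodysplasin receptor gene Edar, Sos2, Rapgef4, Srsf3, C77080, Plscr2 and Cpa2, from 3.16 to 4.40. The lowest were regions of Myo1d (-4.39 ± 0.27), Exoc4 (-3.97 ± 0.26), Col4a3, Kat2b, Igll1, Tmtc1, Myo5a, Ubtd1, Col9a3 and Naip2, the last 8 from -3.78 to -3.17. In all, 24512 regions were higher and 21127 lower, of which 13528 and 13995 by at least 2-fold. The Trp53 regions did not pass, with log2 fold changes from -0.18 to 0.05.

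Of all promoters, 20.97% were higher and 8.95% lower. Of the lists, p53 targets and epithelial genes passed limma's camera test and the others did not, with Benjamini-Hochberg adjusted p from 0.0909 for germline genes (0.29 for one-carbon genes) to 0.966 for imprinted genes. Of 49 p53 targets, 18 were lower and 4 higher, also adjusted over the list alone, the highest being Gdf15 at 2.18 ± 0.22 (limma camera, Benjamini-Hochberg adjusted p = 7.43e-06, but adjusted p = 0.559 with an estimated correlation). Epithelial genes were higher in 7 and lower in 1 of 17, also adjusted over the list alone (median 0.67, but -0.24 as deposited; limma camera Benjamini-Hochberg adjusted p = 0.0412, and adjusted p = 0.398 with an estimated correlation). The list did not pass without shp53_AZA replicate 2 or shCTR_AZA replicate 3, or with shared promoter regions entered once (adjusted p = 0.0513 by limma's camera and Benjamini-Hochberg). Krt19 was at 0.97 ± 0.14, Krt18 at 0.93 ± 0.13, Elf3 at 0.70 ± 0.12 and the adhesion gene Epcam at 2.74 ± 0.56. One-carbon genes were higher in 10 and lower in 1 of 33. They included the cystathionine lyase gene Cth at 3.71 ± 0.52, Aldh1l2 at 1.16 ± 0.17, Mthfd2 at 0.69 ± 0.11 and Mthfd1l at 0.51 ± 0.10. Germline genes were higher in 7 and lower in 1 of 13, with Hormad2 at 3.48 ± 0.56 and Stag3 at 1.94 ± 0.41. R-loop factors were higher in 7 and lower in 4 of 42 (6 and 4 adjusted over the list alone), with Chek1 at 1.28 ± 0.15, Mus81 at 0.54 ± 0.09, Atrip at 0.53 ± 0.11 and the topoisomerase gene Top1 at -0.42 ± 0.10. Interferon genes were higher in 5 and lower in 3 of 32, with H2-K1 (0.91 ± 0.12), Bst2 (0.86 ± 0.15), Mavs (0.35 ± 0.08) and Oas1b (-0.73 ± 0.15). Cell cycle genes were higher in 7 and lower in 3 of 37 (3 higher adjusted over the list alone), with Ccnb2 at 0.81 ± 0.11, Mcm6 at 0.71 ± 0.14 and Rrm2 at 0.62 ± 0.16.

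Mesenchymal genes were higher in 4 and lower in 1 of 18, with Thbs1 (0.93 ± 0.12), Serpine1 (0.95 ± 0.18), Sparc (0.68 ± 0.15) and the protease gene Mmp14 (-0.72 ± 0.15). The fibroblast markers Col3a1 (0.86 ± 0.14) and Pdgfrb (1.36 ± 0.28) were both higher. The methylation machinery had 3 higher and 4 lower of 38, with Kdm5b at 0.83 ± 0.23 and the histone methyltransferase genes Dot1l at -0.48 ± 0.10 and Suv39h1 at -0.61 ± 0.15. The remaining counts of higher and lower were 2 and 2 of 14 HOX genes, 3 and 2 of 18 housekeeping genes (2 and 2 adjusted over the list alone), 2 higher of 12 AP-1 genes (1 adjusted over the list alone), and 1 and 1 of 15 imprinted genes, of 6 protocadherins, of 3 endothelial markers and of 4 acinar and endocrine genes. No immune marker of 4 passed in limma, with 1 higher and 1 lower at an unadjusted p under 0.05. Medians above 0 went with a camera direction below other promoters for imprinted, protocadherin, methylation machinery, endothelial (mean -0.23), acinar and housekeeping genes, and the AP-1 median of -0.10 with a mean of 0.01. The median of CpG-island regions was 0.10 (limma camera Benjamini-Hochberg adjusted p = 0.0391, but adjusted p = 0.648 with an estimated correlation), and it was below 0 with library totals (-0.04), with cyclic loess (-0.02) and as deposited (-0.81). So were the medians of promoters and of the lists for cell cycle, R-loop, one-carbon, mesenchymal, methylation machinery and housekeeping genes. CpG-island regions did not pass without either shCTR_NT library, without shCTR_AZA replicate 2, or without shp53_AZA replicate 3, where their median was 0.01. The median of all regions was -0.91 as deposited and -0.15 with library totals, against -0.02 as scaled, so that without scaling 67394 regions were lower and 5705 higher, and of the list members named as higher only Gdf15, Cth, Epcam, Hormad2 and Stag3 passed. Libraries did not overlap in 71.5% of regions (33.3% by chance), and the count of 45639 changed regions became 28038 without shCTR_AZA replicate 3.

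The interaction asked where the drug response differed between p53-shRNA and control-shRNA cells. It passed at 4536 regions, of which 1620 responded more positively in p53-shRNA cells and 2916 more negatively. More negative responses did not prevail with a mean of at least 50 (1202 positive and 984 negative) or after cyclic loess (1615 and 1599). Nor did they without either shp53_NT library. An intronic region of Wdr67 had the largest positive difference (log2 2.53 ± 0.30, limma, Benjamini-Hochberg adjusted p = 0.000219), followed by a region within Fos, the AP-1 transcription factor gene (chromosome 12, 85476068 to 85476478, 2.41 ± 0.24), and by Dera (2.41 ± 0.34), Arfgap3, Prl2c5, the cytokine gene Lif, Zfhx3, Etv6, Smim3 and Prkab1, from 2.23 to 2.39. Pter had the largest negative difference (-2.69 ± 0.38), followed by the histone methyltransferase gene Suv420h1 (-2.50 ± 0.41), Hivep1, Msantd4, Parg, which removes poly-ADP-ribose, Ubr1, Snupn, Tmprss11c, Sorcs1 and Fars2, from -2.38 to -2.22. By the separate contrasts, 2632 of the regions were called in p53-shRNA cells and not in control-shRNA cells, 1153 the reverse, and 462 were called in both with opposite directions.

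Among list members, Cdkn1a at its start (1.27 ± 0.32), Cd80 (1.07 ± 0.25), Mx2 (0.96 ± 0.21), Psmb8 (1.41 ± 0.35) and Ifit1 (2.36 ± 0.65) passed with a more positive response in p53-shRNA cells. Slc19a2 (-0.72 ± 0.17), Ccnb1 (-0.92 ± 0.19), Fanca (-0.61 ± 0.16), Aldh1l2 (-0.89 ± 0.24) and Nnmt (-1.16 ± 0.27) passed with a more negative one. Each of these 10 lost its call without shCTR_AZA replicate 3, and all but Mx2 also without shCTR_AZA replicate 2. The Mdm2 region 27467 bp downstream kept its call without each library (3.48 ± 0.57). The Trp53 regions did not pass, with differences from -0.31 to 0.01. The list of interferon genes had 3 of 32 members past the test, all positive (5 positive and 1 negative adjusted over the list alone; median 0.21, -0.28 as deposited; limma camera Benjamini-Hochberg adjusted p = 6.81e-11, but adjusted p = 0.158 with an estimated correlation). Germline genes had a median of 0.60 with no member past the limma test and 1 at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 7.43e-06, but adjusted p = 0.158 with an estimated correlation), Hormad2 at 2.04 ± 0.79. Hormad2 reached the minimum coverage of 10 only in the shp53_AZA libraries, so its selection favours a positive difference. Protocadherins had a median of 0.33, -0.14 as deposited, with no member past the limma test and 1 at an unadjusted p under 0.05 (limma camera Benjamini-Hochberg adjusted p = 0.0491, but adjusted p = 0.433 with an estimated correlation), Pcdhga12 at 1.56 ± 0.61. After cyclic loess neither the germline nor the protocadherin list passed, nor did CpG-island regions or promoters (medians -0.08 and -0.06). The protocadherin list also lost its call without shCTR_NT replicate 2, shCTR_AZA replicate 3, either shp53_AZA library or shp53_NT replicate 3, and with shared promoter regions entered once (adjusted p = 0.0647 by limma's camera and Benjamini-Hochberg). Of the other lists p53 targets had 2 members positive and 1 negative (2 and 3 adjusted over the list alone), one-carbon genes 2 negative, R-loop factors and cell cycle genes 1 negative each and HOX genes 1 positive (1 and 1 adjusted over the list alone). In the imprinted, epithelial, mesenchymal, endothelial, acinar, AP-1, housekeeping and immune lists no member passed the limma test, with up to 3 members at an unadjusted p under 0.05, nor in the methylation machinery, with 8. Adjusted over the list alone, 1 immune marker was positive and 1 negative. Medians below 0 went with a camera direction above other promoters for p53 targets and for imprinted, epithelial, AP-1, HOX, housekeeping and immune genes, the immune mean being 0.37. CpG-island regions had a median of -0.24 (limma camera Benjamini-Hochberg adjusted p = 2.96e-09, but adjusted p = 0.295 with an estimated correlation) and promoters one of -0.22 (limma camera Benjamini-Hochberg adjusted p = 7.19e-07, but adjusted p = 0.295 with an estimated correlation).

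The interaction count rested on single libraries and on the model. It was 2967 without shCTR_NT replicate 2, 1661 without shCTR_NT replicate 3, 778 without shCTR_AZA replicate 2, 1477 without shCTR_AZA replicate 3, 1745 without shp53_NT replicate 2, 2239 without shp53_NT replicate 3 and 7641 without shp53_AZA replicate 3. Limma without a trend of variance on signal gave 0 calls, with 18441 regions at an unadjusted p under 0.05 against 22087 with the trend. Of the 20 regions named for the largest differences, Etv6, Prl2c5 and Fars2 lost their call without shCTR_AZA replicate 2 and Smim3 without shCTR_AZA replicate 3.

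Fold changes of the separate contrasts were related across the 104719 regions, which are not independent replicates. The drug effects in control-shRNA and p53-shRNA cells, which share no library, correlated at r = 0.63 (Spearman rho = 0.51). From the separate counts 2692 regions would be expected to rise in both and 8957 did, and 4866 fell in both against 1517. Marf1, Cblb, Iars2, Stag3 and Tex19.1 were among the shared rises and Hoxd4, Junb and Gapdh among the shared falls. The knockdown effects without and with the drug, also from separate libraries, correlated at r = 0.77, with 18459 regions higher in both against 7068 expected and 14561 lower in both against 5359. Of the 26561 regions that fell with knockdown, 54.8% were also lower under the drug, including those at the start of Cdkn1a and of Myo1d, Exoc4, Igll1, Kat2b and Ubtd1 and 6 of the 8 of Mdm2, and of the 30195 that rose, 61.1% were also higher, including those near Col1a1 and Shf. Knockdown and drug effects against the same untreated controls correlated at r = 0.38, where 20 simulations of unchanged groups against those controls gave 0.50. Their covariance, 0.361, exceeded the simulated 0.0623 by 0.299, while 7062 regions rose in both against 4151 expected and 2735 fell in both against 2014, of which part may come from the shared controls. Of the regions called in either, 63.7% had the same direction in both. The simulations gave 66.7%, but over all regions, called or not, so these shares cannot be compared.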

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

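The tests of the fall of CpG-island regions in the 5 groups of strongest signal, of weak CpG-island regions and of background in the loss of signal were chosen only after the result was seen. The patterns were picked from the fold changes, and the bounds of the other tests were set before their values were computed. Intervals in this part treat regions, or the 10 groups by signal, as independent and do not measure the spread between libraries. The results singled out here are those where the drug response was tested as different between control-shRNA and p53-shRNA cells by an interaction term.

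The interaction passed at 4536 regions (limma, Benjamini-Hochberg). The more positive responses in p53-shRNA cells, as differences of log2 fold changes, were 2.53 at Wdr67, 2.41 at Fos, 2.41 at Dera, 2.39 at Arfgap3, 2.34 at Prl2c5, 2.34 at Lif, 2.27 at Zfhx3, 2.26 at Etv6, 2.23 at Smim3 and 2.23 at Prkab1. The more negative ones were -2.69 at Pter, -2.50 at Suv420h1, -2.38 at Hivep1, -2.37 at Msantd4, -2.32 at Parg, -2.31 at Ubr1, -2.30 at Snupn, -2.29 at Tmprss11c, -2.25 at Sorcs1 and -2.22 at Fars2. Without shCTR_AZA replicate 2, where the count was 778, Prl2c5, Etv6 and Fars2 did not pass, and Smim3 did not without shCTR_AZA replicate 3. The median difference was 0.601 for germline genes, 0.212 for interferon and viral sensing genes and 0.325 for clustered protocadherins, and none of these 3 lists passed with an estimated correlation.

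One pattern was that strong regions and CpG-island regions fell after the drug while weak regions rose, with either shRNA. A lower ratio of signal to background would press all regions towards one level, and the 90th percentile of coverage over the median without an interval went from 12.6 and 13.7 to 10.005 and 10.1 in control-shRNA cells and from 17.5 and 16.2 to 8.52 and 9.63 in p53-shRNA cells. The tables argue against it as the source of all rises. After cyclic loess removed the trend on signal, 88.1% as many regions rose in control-shRNA cells. Of the risen regions themselves, 11656 of 14397 stayed higher there and 13771 of 19582 in p53-shRNA cells. In the 5 groups of strongest signal, CpG-island regions lay below other regions of equal signal. After cyclic loess the difference closest to 0 was -0.142 (95% interval -0.153 to -0.133), in the strongest group of control-shRNA cells. Cyclic loess moves regions of equal signal alike, so it could hardly change this difference (medians -0.267 against -0.123 without it). The difference argues against a trend on signal alone as the whole cause of these falls. A background effect that differs between CpG islands and other regions was not tested. Over all 10 groups the mean difference was -0.0970 (-0.511 to 0.317), since weak and strong CpG-island regions moved apart, so that a part played by background and a response to the drug cannot be told apart there.

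Another pattern was the loss of signal in untreated p53-shRNA cells. Around the 448 fallen regions with a p53 element, a lost chromosome segment is argued against. There, 3355 regions without the element within 50 kb had a median log2 fold change of 0.03 (0.0276, -0.0140 to 0.0674), where the element regions had -1.91. The surroundings of the other fallen regions were not examined. Loss of p53 at its elements, the biological explanation that the design names, passed a test that could have failed, as 1.69% of fallen regions held the element against 0.648% of regions not called (odds ratio 2.64, 2.28 to 3.06, within strata of signal). By the bound set beforehand, base composition cannot be told apart by the reversed consensus, whose odds ratio of 1.17 (0.737 to 1.85) has too wide an interval. That interval lies wholly below that of the element, however, which argues against base composition as the whole source of the element's excess. The rough measure of signal over background was higher in shp53_NT (17.5 and 16.2) than in shCTR_NT (12.6 and 13.7), and 43.8% of regions fell in the weakest of 10 groups by signal against 8.43% in the strongest. As the source of all falls this is argued against, since 70.2% of the fallen regions (69.6 to 70.7) were still called lower after cyclic loess removed the trend on signal, but the other falls may be due to it. As 448 of 26561 fallen regions held the element, no test accounts for most of the loss.

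The last pattern was the gain of signal with the drug in control-shRNA cells. Reads of repeats that cannot be placed are argued against, since 14.7% of regions with under 5% repeat bases rose and 13.3% of those with over 50% (ratio 1.10, 1.02 to 1.19). Weak CpG-island regions had higher medians than other regions of equal signal, 1.06 against 0.323 in control-shRNA cells and 2.58 against 0.822 in p53-shRNA cells, the smaller difference being 0.736 (0.517 to 0.906). In control-shRNA cells, however, 21.1% of them were called higher against 21.4% of the others, unlike the 80.3% against 33.5% in p53-shRNA cells, so that a larger part of weak CpG islands in the called rises stays open. Groups of equal signal were formed by mean coverage over all 8 libraries, treated ones included, with a mean of 9.35 in the weakest. As testing needed a coverage of at least 10 in 2 libraries, weak regions can enter through a rise in the treated ones. That selection may add to these differences, and its part was not tested. Whether demethylation of binding sites with CpGs took part cannot be told, as the odds ratio of the NRF1 site outside CpG islands was 1.76 (1.48 to 2.103, against 0.938 for the reversed sequence), between the bounds of 1.2 and 2 set beforehand. The reversed sequence lay in only 9 of the risen regions, and its interval (0.463 to 1.90) overlaps that of the site. In p53-shRNA cells, for which no bound was set, the odds ratio of the NRF1 site was 2.36 (1.98 to 2.81, against 0.688). Over all regions, CpG islands included, it was 0.567 (0.486 to 0.661, against 0.149) in control-shRNA cells, the opposite direction, and 1.26 (1.09 to 1.46, against 0.337) in p53-shRNA cells. DNA methylation was not measured, so a link of the rises to methylation remains a hypothesis.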

How the results depend on the processing

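The tests on the highest coverage in place of the mean and on shared promoter regions entered once were chosen only after the result was seen. All alternatives ran except those for counts (edgeR, DESeq2 and its size factors), as the file holds none, and median centring stood in for the latter. Read depth is unknown, and coverage summed over regions was lowest in shp53_AZA. With 2 libraries per group, leaving out 1 leaves a lone sample, which is assumed to vary like the other groups. Where no reason is given the cause was not tested.

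Fewer regions tested gave, with a mean of at least 50, 18742 calls for knockdown in untreated cells (56756), 7003 for the drug in control-shRNA cells (22339), 9781 in p53-shRNA cells (39581), 16049 for knockdown under the drug (45639) and 2186 for the interaction (4536). In that order, the log2 minimum of 1, stricter by construction, gave 35415, 11703, 18799, 27523 and 2986. Limma without a trend gave 11554 and 24994 for the drug effects and 0 for the interaction, with 18441 regions at an unadjusted p under 0.05. A pseudocount of 5 gave 7159 for the interaction. Values as deposited gave 73099 for knockdown under the drug and 26350 for the interaction. Leaving out each library gave 42294 to 60717, 8334 to 27747, 28319 to 40681, 28038 to 45728 and 778 to 7641, in the same order. The highest coverage gave 54074, 19324, 36831, 43690 and 3775. Fits of only the 4 libraries of a contrast, which exist for the pairwise contrasts alone, gave 59335, 33191, 33549 and 42951. The correlation of drug effects was 0.705 over regions called in either, that of knockdown and drug effects 0.499 after cyclic loess, and that of knockdown effects 0.851 with a mean of at least 50.

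Scaling moved the share of higher calls. For knockdown in untreated cells it was 53.2%, but 41.3% with library totals and 26.9% as deposited. For knockdown under the drug it was 53.7%, 42.1% and 7.80%. For the drug in p53-shRNA cells it was 49.5%, 60.5% and 23.4%, in control-shRNA cells 64.4% and, as deposited, 81.6%, and for the interaction 35.7%, 50.2% after cyclic loess and 3.98% as deposited.

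Named regions turned mostly as deposited. For knockdown under the drug these were Atrip -0.39, Bst2 -0.05, Ccnb2 -0.11, Cdkn1a (4052 bp) -0.84, Col3a1 -0.05, Elf3 -0.21, H2-K1 -0.01, Kdm5b -0.06, Mavs -0.58, Mcm6 -0.20, Mdm2 (7060 bp upstream) -0.62, Mthfd1l -0.41, Mthfd2 -0.22, Mus81 -0.38, Rrm2 -0.29, Sparc -0.23 and Trp53 (1050 bp upstream) -0.87. For knockdown in untreated cells they were Mdm2 -0.39 and Trp53 -0.38 at the same regions, which were -0.30 and -0.31 after cyclic loess. For the drug in p53-shRNA cells, Trp53 (1050 bp upstream) was 0.12 after cyclic loess and 0.04 with a mean of at least 50, and Cdkn1a (2759 bp) 0.08 and 0.00. In the interaction that Trp53 region was -0.49 as deposited. Of the results for named regions, 278 were the same as deposited (call and, where called, direction), while 29 lost their call, 13 gained one and 20 turned. The number that stayed the same was 295 after cyclic loess, 330 with library totals, 337 with median centring, 330 with the highest coverage and 273 without a trend.

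Of 85 list tests, 76 were the same after cyclic loess, 83 with library totals, 81 with each shared promoter region entered once and 65 over all regions of the genes. In the last, medians of housekeeping genes were 0.217 and 0.421 for knockdown with and without the drug and that of immune markers -0.155 for the drug in control-shRNA cells, with the direction of the test turned. The AP-1 median in p53-shRNA cells was 0.018 after cyclic loess. For knockdown under the drug, CpG-island regions had a median of -0.018 after cyclic loess and of 0.006 to 0.215 without each library. Fry was run for the lists but is not given, since it tests against no change and not against other promoters. Samples with the same number did not deviate together (correlations -0.0193 to 0.0287), and a replicate block gave 56778, 22456, 39692, 45697 and 4477 calls, with all 85 list tests unchanged.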

Other observations

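The motif counts below were chosen only after the result was seen, that is, after the fold changes, and had no bound set beforehand except for the p53 and NRF1 sites. Consensus sites are counted, not bound factors, and all odds ratios are against regions not called, within strata of mean signal. Their intervals treat regions as independent and do not measure the spread between libraries.

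Regions that opened and closed with the drug differed in AP-1 sites. These lay in 47.5% of the regions that rose with the drug in control-shRNA cells and in 35.4% of those not called (odds ratio 1.76, 1.70 to 1.82, against 1.40 for the reversed sequence). In p53-shRNA cells the odds ratio for rises was 1.38 (1.34 to 1.43), close to the 1.26 of the reversed sequence. They lay in 25.8% of the regions that fell in control-shRNA cells (0.509, 0.481 to 0.538, against 0.791) and in 29.1% of those that fell in p53-shRNA cells (0.480, 0.462 to 0.4998, against 0.770). The site of CTCF, the insulator protein, was rarer than in regions not called both where the drug raised and where it lowered signal. It lay in 4.74% of those that rose with the drug in control-shRNA cells, against 17.5% of those not called (0.239, 0.221 to 0.259), and in 10.5% of those that fell (0.595, 0.550 to 0.643). In p53-shRNA cells it lay in 8.12% of those that rose (0.408, 0.386 to 0.431) and in 12.2% of those that fell (0.656, 0.622 to 0.692). With knockdown in untreated cells it lay in 7.92% of the higher (0.367, 0.349 to 0.386) and in 19.95% of the lower regions (1.27, 1.22 to 1.32).

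RUNX sites lay in 20.8% of the regions that fell with knockdown in untreated cells, against 13.03% of those not called (odds ratio 1.80, 1.73 to 1.87, against 1.13 for the reversed sequence). Under the drug the values were 20.5% and 13.6% (1.64, 1.58 to 1.71, against 1.18). The p53 element lay in 1.73% of regions lower with knockdown under the drug, against 0.708% of those not called (2.42, 2.103 to 2.79, against 0.904 for the reversed consensus). It was rarer than in regions not called among those that rose with knockdown in untreated cells (0.629, 0.508 to 0.778), though the interval of the reversed consensus overlaps (0.756, 0.488 to 1.17).

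The authors' deposited adjusted p-values called 35375 regions for knockdown in untreated cells, of which 99.6% were also called here. For the drug in control-shRNA cells these were 15793 and 88.6%, in p53-shRNA cells 15557 and 99.9%, and for knockdown under the drug 27608 and 98.0%. More regions were called here, so the reverse shares were lower. The deposited values also called 35184 of 56756 regions for knockdown in untreated cells and 26787 of 45639 under the drug. For the drug they also called 13964 of 22339 in control-shRNA cells and 15420 of 39581 in p53-shRNA cells. All regions called in both had the same direction in these 4 comparisons, and deposited and recomputed log2 fold changes correlated at 0.943 to 0.980.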
